A study of Mus musculus with 2 samples.

How the data were processed

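The series holds 2 single-cell RNA libraries, 1 per group, of donor CD4 T cells sorted from the lungs of recipient mice. Donor mice were wild type in both groups; the hosts were wild type (C57BL/6) in one group and deficient in MARCH1 in the other, and they are called the WT host and the MARCH1-/- host below. MARCH1 is a membrane-bound ubiquitin ligase of antigen-presenting cells that lowers surface MHC class II and CD86. Per the labels' protocols the libraries were made with the 10x Chromium Next GEM 3' kit (v3.1), which reads the 3' ends of polyadenylated transcripts and tags each captured molecule with a unique molecular identifier (UMI).

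The deposited matrices hold whole-number counts of UMIs per gene and barcode, with no normalization, for 32285 genes and for every barcode, before any call of cells. Counting was done with Cell Ranger 3.1.0 on build mm10 per the submitters' processing notes, while the matrix headers name version 4 of the same program; which of them made the deposited counts is not given in the sources used here, nor is the gene annotation. Gene symbols and IDs come from the deposited gene tables. Positions, gene types, transcript lengths and GC content were taken from the GENCODE M21 annotation of GRCm38 (mm10), matched by gene ID, and 99.9% of the 6689 genes with at least 50 UMIs had a match.

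Barcodes were called as cells when they held at least 500 UMIs, at least 250 detected genes and at most 10% mitochondrial UMIs. Doublets were called with Scrublet in each library (expected rate 0.05) and removed: 1 of 352 called barcodes (0.284%) in the WT-host library and 6 of 156 (3.85%) in the MARCH1-/- host library. Both libraries were clustered together without integration in scanpy 1.11.5: total-count scaling to 10000, log transform, 2000 highly variable genes, 20 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 0.5 with seed 1. The leading genes of a cluster were the 10 with the highest fold of its CPM (plus 20) over that of the other cells, among genes seen in at least 10% of its cells. A cluster was named only if at least 3 of these were markers of one class and at most 1 was a marker of another. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

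From the deposited counts, UMIs were summed over the cells of each library and scaled to their total as counts per 1e6 UMIs (CPM). With 1 library per group there is no replicate, so no test was run and no p-value is given. Sums carry exact Poisson 95% intervals, ratios exact conditional binomial intervals, and shares of cells exact binomial (Clopper-Pearson) intervals. All of them cover counting error only, not the difference between animals or library preparations. Intervals of sums and ratios treat each UMI as an independent draw, so they also leave out variation between cells. For genes whose UMIs sit in few cells they are too narrow. Ratios are log2 of the MARCH1-/- host over the WT host. A gene at 0 UMIs on one side enters a list at a floor of 3 counts. The median of a gene list was taken over members with at least 10 UMIs in all, with an interval from 1000 Poisson redraws of the counts, and is given with its percentile among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. Shares of cells with a UMI were computed after each cell was thinned to 1000 UMIs in 1 random draw, which left out 11 of 351 cells of the WT-host library and 0 of 150 of the other; the share expected over all draws and the unthinned share are given too.

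Fixed before the data were examined were the cell filters, the clustering settings, the gene lists, the markers and the rule for named genes. The lists were co-inhibitory receptors, exhaustion-associated regulators, T cell receptor response, type 2 helper (Th2), regulatory T (Treg), cell cycle, type 1 helper and cytotoxic, type 17 helper (Th17), follicular helper (Tfh), naive and central memory, tissue residency and migration, costimulatory receptors, interferon response, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, cholesterol and lipid synthesis, unfolded protein response, apoptosis and p53, dissociation and heat shock, and sex-linked genes. Some genes stand in several lists. The named genes were March1, then Pdcd1, Lag3, Tigit, Havcr2, Ctla4, Tox, Nr4a1, Nr4a2, Nr4a3, Il4, Il5, Il13, Il10, Ifng, Foxp3 and Gata3, then the 12 genes higher and the 12 lower in the MARCH1-/- host library whose counting interval lay farthest from no change. Those 24 needed at least 50 UMIs, a UMI in at least 5% of the cells of the library with the higher value and the same direction in the mean of per-cell CPM; ribosomal protein, mitochondrial, haemoglobin, immunoglobulin, T cell receptor segment and unnamed genes were left out of them and described as classes. Up to 4 further members of each list with the most UMIs could be named, and other list members named in the text were chosen after their values were seen. Some genes that the rule or the lists hold are not reported here. A gene was marked as sharing sequence when a stretch of 50 bases in the last 600 nt of its longest transcript also occurred in a transcript of another gene, since the authors' counting could split or drop such reads.

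Free RNA was estimated from barcodes under 100 UMIs, which held 28.9% of the UMIs of the WT-host library and 16.9% of the other. At the 99th percentile such a barcode held 22 and 10 UMIs, or 0.371% and 0.128% of the median cell. These barcodes also held T cell RNA, so a planned fit of their share on genes of other cell types was not usable: 52 such genes made up 54.4 CPM of the low barcodes and 53.1 CPM of the cells in the WT-host library, and 116 and 59.4 CPM in the other.

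The ratio, interval and list steps were tested on simulated data drawn for the comparison of the MARCH1-/- host with the WT host. Intervals covered the true value for 95.6% of 6489 unchanged genes and for 98%, 96%, 98% and 94% of the 50 genes each changed 1.5-, 2-, 4- and 8-fold, with the direction right for 100% of each. A simulated list of 20 unchanged genes had a median log2 ratio of 0.05 (percentile 83.8) and a list of 20 genes raised 2-fold had 0.92 (percentile 100). The simulated sums were Poisson draws per library, with no variation between cells and no library effect. Coverage near 95% was thus built in, and it checks the computation only, not how the intervals perform on the real counts. Alternatives covered cell filters, doublets, clustering resolution, thinning, scaling, weighting of cells, the member minimum, free RNA, gene properties and subsets of cells; their effect is given in the closing section.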

Results

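Donor mice were sensitized with house dust mite extract, an allergen that drives type 2 airway inflammation, on day 0 and again on days 7 to 11. On day 14 CD4 T cells from their lungs were labelled with Cell Trace Violet, a dye diluted at each division, and given to hosts with or without MARCH1. The hosts were challenged with the extract, and at day 4 the dye-low donor cells, those that had divided, were sorted from the lung. The comparison asks whether MARCH1 in the host alters the exhaustion-like program of these effector cells, exhaustion being a state with many inhibitory receptors and lower cytokine output. There was 1 library per group, so every difference below is between 2 libraries and has no replicate check.

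The WT-host library held 3753437 UMIs and gave 351 cells after doublet removal, with a median of 5937 UMIs (quartiles 3904 and 9218) and 1975 genes per cell. The MARCH1-/- host library held 1934068 UMIs and gave 150 cells, with a median of 7830 UMIs (quartiles 5066 and 11762) and 2493 genes. Cells held 68.2% and 76.6% of each library's UMIs, and their median mitochondrial share was 2.38% and 2.66%. The mitochondrial limit removed 73 barcodes (17.2% of those with at least 500 UMIs) and 26 (14.3%). All 5 clusters had all 12 CD4 T cell markers and were kept as T-like by the planned rule, which at this ceiling cannot show that each cell is a T cell. Summed over cells, the CD4 T cell markers came to 4743 and 6448 CPM, against 44.1 and 145 CPM for B cell, 316 and 356 CPM for macrophage and monocyte, 112 and 51.3 CPM for CD8 T cell and 2.73 and 3.38 CPM for NK cell markers. The innate lymphoid (ILC2) markers, many of which Th2 cells also express, came to 1756 and 1938 CPM. The higher CD4 T cell marker sum in the MARCH1-/- host library did not hold for Cd4 itself. Cd4 was seen in 36.8% (31.6 to 42.1) of thinned cells from WT hosts and 25.3% (18.6 to 33.1) from MARCH1-/- hosts. Unthinned, the shares were 85.2% and 80%.

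March1 (ENSMUSG00000036469, a protein-coding gene on chromosome 8, 65617900 to 66471637, GRCm38) had 0 UMIs in all barcodes of both libraries. The upper bounds of its exact Poisson intervals were 1.44 CPM in the cells from WT hosts and 2.49 CPM in those from MARCH1-/- hosts. Donor cells were wild type in both groups, so its level checks nothing about the hosts. The 6689 genes with at least 50 UMIs had a median log2 ratio of 0.25, while ribosomal protein genes took 27.7% of UMIs in the WT-host and 22.6% in the MARCH1-/- host library. Mitochondrially encoded genes took 2.45% and 2.67% of UMIs, histone cluster genes 0.662% and 0.469%, and immunoglobulin genes 0.00320% and 0.0113%; haemoglobin genes had 1 and 2 UMIs, and T cell receptor beta and alpha variable segments had log2 ratios of -1.03 and -1.67. Values called relative below have the 0.25 of this median gene subtracted.

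In cells from MARCH1-/- hosts the inhibitory receptors Pdcd1 (PD-1) and Lag3, summed over all cells, were near the level of the WT-host library, Tigit and Havcr2 (TIM-3) were lower, and Ctla4 was higher. Pdcd1 was at 199 CPM (182 to 217) in the WT-host and 194 CPM (172 to 218) in the MARCH1-/- host library, a log2 ratio of -0.04 (-0.25 to 0.17). Within the cycling-like cluster Pdcd1 was at a log2 ratio of -0.46 (-0.87 to -0.05) and without it at 0.31 (0.06 to 0.56), and it was at 0.22 (-0.42 to 0.84) when cells were thinned to 1000 UMIs. Lag3 was at 109 CPM (96.2 to 122) and 105 CPM (89.4 to 123), a log2 ratio of -0.04 (-0.34 to 0.24), and at -0.69 (-1.75 to 0.25, 44 and 12 UMIs) in the thinned draw. Tigit, a receptor that competes for CD226 ligands, was at 32.8 CPM (26.2 to 40.6) against 3.38 CPM (1.10 to 7.88), from 84 and 5 UMIs, a 9.72-fold (4.00 to 30.7) higher level in the WT-host library (log2 ratio -3.28). Thinned, it had 18 and 0 UMIs, which gives no ratio. Havcr2 was at 78.1 against 43.2 CPM (log2 ratio -0.85, -1.28 to -0.44), but without the cycling-like cluster at -0.31 (-0.76 to 0.12), an interval that includes no difference. Ctla4, which binds CD80 and CD86, was at 565 CPM (536 to 595) against 936 CPM (887 to 986), a log2 ratio of 0.73 or 0.48 relative to the median gene.

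Among the transcription factors tied to exhaustion, Tox was lower in cells from MARCH1-/- hosts. Of the Nr4a family, induced by T cell receptor signals, Nr4a1 and Nr4a2 were higher summed over all unthinned cells, and the interval of Nr4a3 included no difference. Tox was at 209 CPM (192 to 227) against 83.7 CPM (69.6 to 99.8), 2.50-fold (2.05 to 3.06) higher in the WT-host library. In barcodes over the mitochondrial limit, which were left out, it was at 693 CPM (520 to 904) against 460 CPM (252 to 772), with overlapping intervals. Nr4a1 was at 88.3 against 120 CPM (log2 ratio 0.44, 0.15 to 0.73; 0.03 without clusters 0 and 4), Nr4a2 at 19.1 against 36.5 CPM (0.93, 0.34 to 1.52), and Nr4a3 at 25 against 16.9 CPM (-0.57, -1.30 to 0.12; 0.86 when thinned, from 10 and 8 UMIs). Ikzf3 (Aiolos, log2 ratio -0.79) and Rgs16, a regulator of G-protein signalling (-0.85), were also lower, while Batf, an AP-1 factor of effector cells, was higher (0.56).

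These genes were protein-coding. On GRCm38 they lay on chromosome 1 (Pdcd1, ENSMUSG00000026285, 94038305 to 94052553, and Ctla4, ENSMUSG00000026011, 60887000 to 60915832), chromosome 6 (Lag3, ENSMUSG00000030124, 124904361 to 124911705), chromosome 16 (Tigit, ENSMUSG00000071552, 43648867 to 43664146), chromosome 11 (Havcr2, ENSMUSG00000020399, 46454935 to 46481255) and chromosome 4 (Tox, ENSMUSG00000041272, 6686353 to 6991557).

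**Figure D1:**
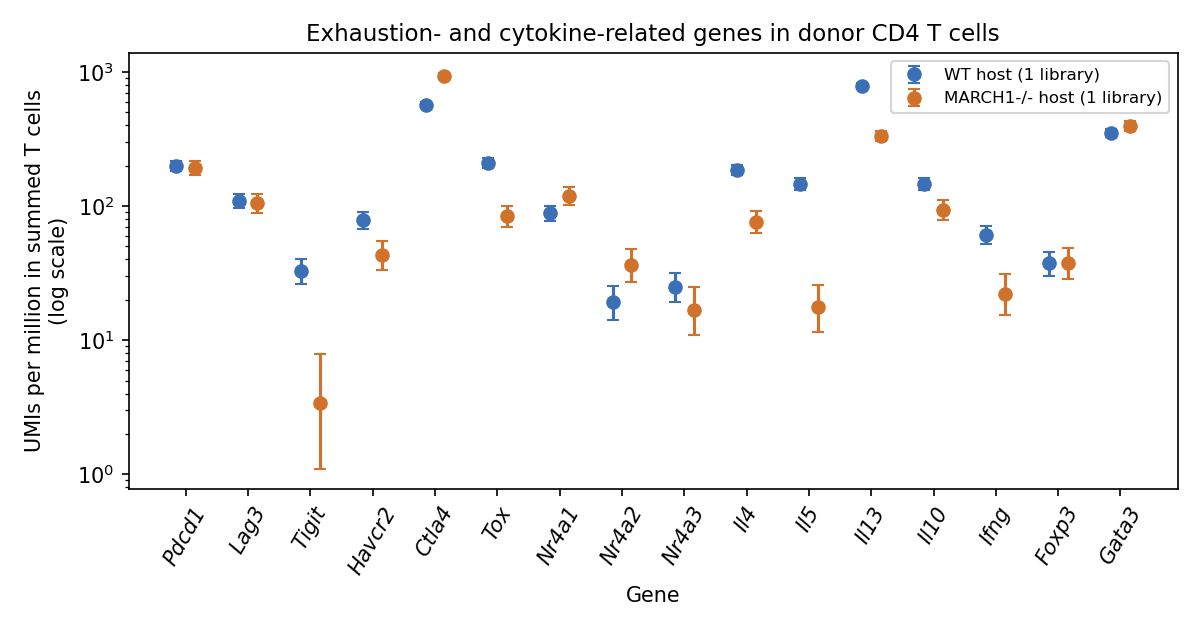
Level of 16 genes fixed in advance (x axis), in CPM summed over the T cells of each library (y axis, log scale), with points for the WT-host and the MARCH1-/- host library and bars for exact Poisson 95% intervals of the counts. Tigit (32.8 against 3.38 CPM) and Il5 (147 against 17.6 CPM) lie farthest apart, and Pdcd1, Lag3 and Foxp3 overlap.

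Taken as lists over all cells, co-inhibitory receptors and exhaustion-associated regulators both lay low in the MARCH1-/- host library relative to other genes. Of the 17 measured co-inhibitory receptors 6 had higher and 11 lower values; the ectoenzymes Entpd1 (CD39, log2 ratio -0.82) and Nt5e (CD73, -0.50) were lower, and Cd5 (0.81) and Btla (1.36) higher. The list's median log2 ratio was -0.13 (-0.36 to 0.07), -0.38 relative to the median gene, at percentile 1.17 of the random lists. Of the 19 regulators 7 had higher and 12 lower values, with a median of -0.16 (-0.33 to 0.02), -0.41 relative, at percentile 0.705. The cycling cells, which held many UMIs each, weighed heavily in these sums: without their cluster the medians were 0.20 and 0.14, or -0.03 and -0.09 relative to the median gene of the remaining cells. Within that cluster they were 0.05 (percentile 13.0) and -0.36 (percentile 0.125). The co-inhibitory median over all cells thus lay below both parts, though it was over 17 members there and without the cluster, and over 15 within it. Whether the number of cycling cells in each library explains this was not tested. With each cell weighted equally the co-inhibitory median was 0.09, and with cells thinned to 1000 UMIs 0.18.

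Over all cells the share with a Pdcd1 or Lag3 UMI showed no difference beyond counting error. After thinning, Pdcd1 was seen in 56 of 340 cells from WT hosts (16.5%, 12.7 to 20.8) and 30 of 150 from MARCH1-/- hosts (20%, 13.9 to 27.3), and over all draws 18.0% and 18.3% were expected; unthinned it was 53.8% and 58.0%. Lag3 was seen in 10.3% (7.28 to 14.0) and 6.67% (3.24 to 11.9), with 9.15% and 9.89% expected and 34.8% and 37.3% unthinned. In 1 draw without the cycling-like cluster Lag3 was at 7.17% (4.43 to 10.9) and 14.8% (8.71 to 22.9), a difference of 7.65 percentage points (0.52 to 16.2), but over all draws the expected difference was 2.26 points. Ctla4 was seen in 35.6% (30.5 to 40.9) against 55.3% (47.0 to 63.5) of thinned cells, and Tox in 22.1% (17.8 to 26.9) against 8.67% (4.70 to 14.4). The unthinned shares were 81.2% and 91.3% for Ctla4 and 56.7% and 47.3% for Tox. Tigit was seen in 5% (2.94 to 7.88) of thinned cells from WT hosts, against 0 of 150 (0%, 0 to 2.43) from MARCH1-/- hosts, with 4.18% and 0.486% expected over all draws; unthinned, 17.1% (13.3 to 21.5) and 3.33% (1.09 to 7.61) of cells had a UMI. At the thinned depth free RNA was estimated to account for at most 0.225% of cells for any of these genes, that for Ctla4 in the WT-host library. It was not estimated for the unthinned shares.

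**Figure D2:**
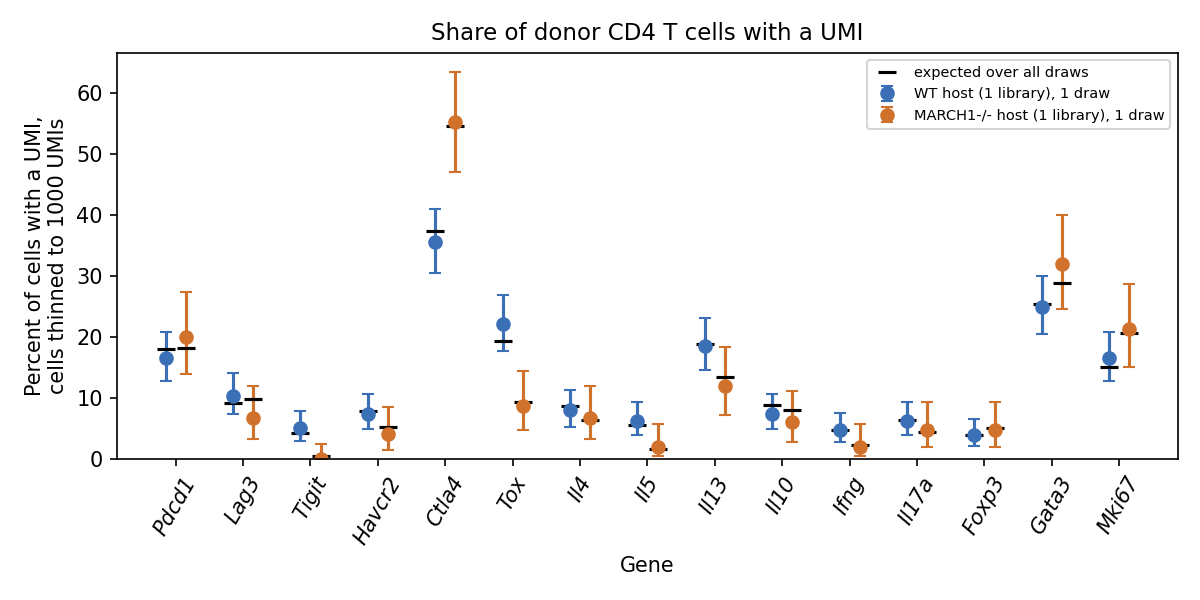
Percent of cells with at least 1 UMI of each gene (y axis, genes on the x axis) after each cell was thinned to 1000 UMIs, in 340 cells from WT hosts and 150 from MARCH1-/- hosts, with points for 1 random draw, bars for exact binomial 95% intervals and black dashes for the share expected over all draws. Ctla4 (35.6% against 55.3%) and Tox (22.1% against 8.67%) have separate intervals, while those of Pdcd1 and Lag3 overlap.

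Type 2 cytokines, which drive eosinophilia and mucus in the allergic airway, were lower in cells from MARCH1-/- hosts. Il4, Il5 and Il13 together were at 1122 CPM (1081 to 1164) in the WT-host and 429 CPM (396 to 463) in the MARCH1-/- host library, 2.62-fold (2.40 to 2.86) higher in the former. Il4 was at 186 against 76.3 CPM (log2 ratio -1.28), Il5, the eosinophil growth factor, at 147 (132 to 162) against 17.6 CPM (11.5 to 25.7; log2 ratio -3.06), and Il13 at 789 (755 to 825) against 335 CPM (306 to 366; -1.24). These 3 genes stand close together on chromosome 11 (Il4, ENSMUSG00000000869, 53602982 to 53618669; Il13, ENSMUSG00000020383, 53631324 to 53634702; Il5, ENSMUSG00000036117, 53720794 to 53725106). Il10, an anti-inflammatory cytokine, was at 146 against 93.8 CPM (-0.64), and Ifng, the type 1 cytokine, at 60.9 against 22.3 CPM (-1.45). Gata3, the Th2 master regulator, was at 349 against 396 CPM (0.18, -0.07 relative to the median gene).

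Cytokine levels differed by cell cluster. In the Th2-like cluster the 3 cytokines were at 2056 CPM (1944 to 2173) in cells from WT hosts and 2438 CPM (2225 to 2666) in those from MARCH1-/- hosts, a log2 ratio of 0.25. Il13, itself among that cluster's leading genes, carried this sum (915 and 401 UMIs, log2 ratio 0.44), Il4 was at 0.15 (-0.28 to 0.57), and Il5 was lower in cells from MARCH1-/- hosts (162 and 16 UMIs, -1.71, -2.55 to -0.97). In the WT-host library 5 of the cluster's 89 cells held 115 of these Il5 UMIs, and 26 of 89 and 8 of 20 cells had any. In the cycling-like cluster they were at 1493 CPM (1412 to 1577) against 95.1 CPM (74.1 to 120), 15.7-fold higher in the WT-host library. In cluster 1 they were at 229 against 77.0 CPM (log2 ratio -1.57), and in cluster 0 at 380 against 23.1 CPM, the latter from 1 UMI in 11 cells (log2 ratio -4.04, -9.35 to -1.55). Without the cycling-like cluster the log2 ratio of the 3 cytokines together was -0.31; Il5 still stood at -2.54, Il4 at -0.47 and Il13 at -0.05 there, and Il10 turned to 0.21. Thinned to 1000 UMIs, Il5 was at -2.25 (-4.19 to -0.79), while Il4 (-0.44, -1.42 to 0.46), Il10 (-0.18, -1.19 to 0.74) and Ifng (-0.82, -2.26 to 0.41) had intervals that include no difference; Il4 was at -0.56 with the length and GC trend removed. At least 1 UMI of the 3 was seen in 23.8% (19.4 to 28.7) and 15.3% (9.98 to 22.1) of thinned cells, with 0.248% and 0.0297% from free RNA at that depth. In unthinned cells it was 39.0% and 37.3%.

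**Figure D3:**
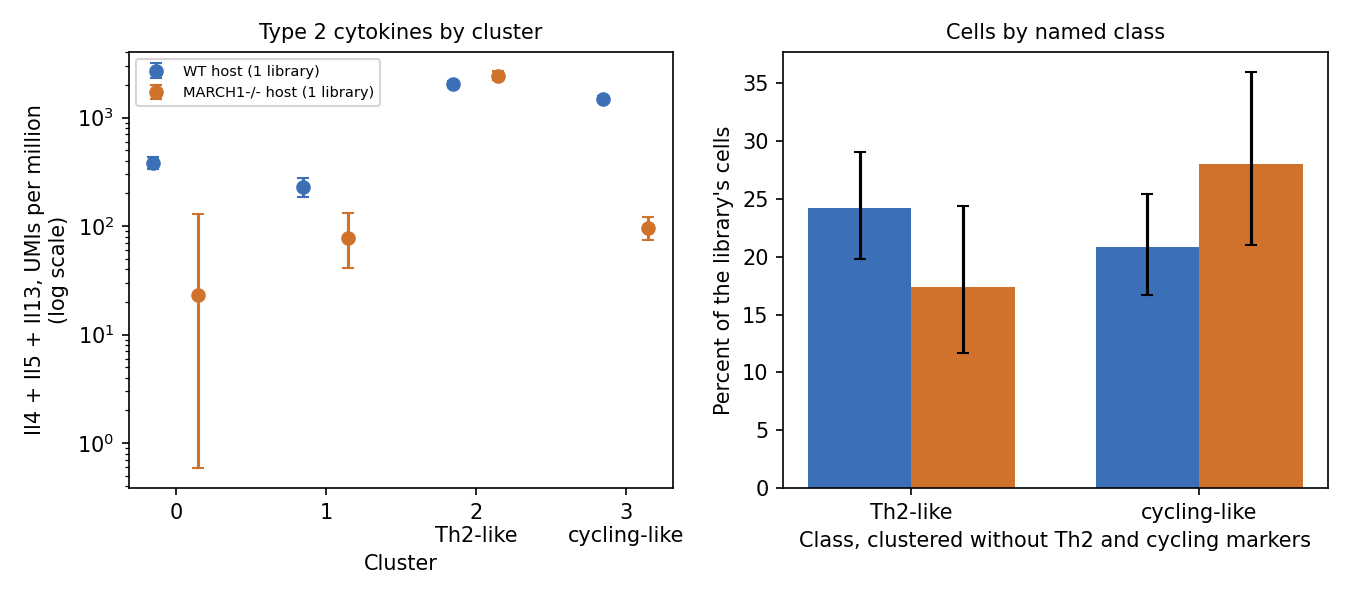
Left, level of Il4, Il5 and Il13 together by cluster (x axis) in CPM (y axis, log scale) with exact Poisson 95% intervals; right, percent of each library's cells in the Th2-like and cycling-like classes, clustered without the Th2 and cycling markers, with exact binomial 95% intervals. The libraries lie far apart in the cycling-like cluster (1493 against 95.1 CPM) and in cluster 0 (380 against 23.1 CPM, from 1 UMI), and close in the Th2-like cluster (2056 against 2438 CPM).

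Of the 20 measured genes of the Th2 list 7 had higher and 13 lower values in the MARCH1-/- host library. Lower were Rbpj, the DNA-binding partner of Notch (848 against 419 CPM, log2 ratio -1.02), Plac8 (-0.79), Calca, which encodes the neuropeptide CGRP (-1.26), and the chemokine receptor Ccr8 (60.9 against 6.08 CPM, -3.33). Ccr4, another chemokine receptor of Th2 cells, was higher (1.32), and Areg, an epithelial growth factor, was at 371 against 413 CPM. The list's median log2 ratio was -0.17 (-0.63 to -0.03), -0.42 relative, at percentile 0.5. Without the cycling-like cluster the median was 0.08, or -0.15 relative at percentile 18.5, with 10 members higher and 10 lower.

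Cell cycle genes as a list were higher in cells from MARCH1-/- hosts: 35 of 37 members had higher values, 30 of them with an interval clear of 0, and 33 lay above the median gene. They included Mki67, the proliferation marker Ki-67 (322 against 497 CPM, log2 ratio 0.62), the DNA topoisomerase Top2a (0.59), the mitotic kinase Cdk1 (1.52), the replication helicase subunit Mcm7 (1.75), the ubiquitin-conjugating enzyme Ube2c (1.15) and the ribonucleotide reductase subunit Rrm2 (1.35); Hells (-0.59) and Cks2 (-0.14) were the 2 lower members. Of these genes, Mki67, Mcm7 and Cks2 share from 11.7% to 34.2% of the 3' sequence searched with other genes, and without all members that share some the list's median was 0.84. The median log2 ratio was 0.63 (0.58 to 0.78), 0.38 relative, at percentile 99.99 of the random lists. Within the cycling-like cluster it was 0.58, or 0.31 relative, with 31 members higher and 6 lower. Outside that cluster the direction turned: the median was -0.50, with 9 members higher and 26 lower. Cell cycle genes lead that cluster and so set its borders. The list's level inside or outside it therefore decides nothing about cycling. Thinned cells with a Mki67 UMI made up 16.5% (12.7 to 20.8) and 21.3% (15.1 to 28.8), and unthinned 37.0% and 45.3%.

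Over all cells, genes that respond to T cell receptor signals showed no common direction relative to other genes, but this depended on the cells taken. Of 25 members 17 had higher and 8 lower values, with a median log2 ratio of 0.26 (0.07 to 0.37), 0.01 relative, at percentile 52.0. The NF-kappa-B inhibitor Nfkbia (1.31), the phosphatase Dusp2 (1.62) and the costimulatory ligand Cd40lg (1.30) were higher in cells from MARCH1-/- hosts, and the interleukin 2 receptor chain Il2ra (323 against 173 CPM, -0.90) and Tnfrsf9 (4-1BB, -0.75) were lower. Without the 5% of cells with the largest share of their UMIs in these genes the median was -0.01. Without the cycling-like cluster it was 0.51, 0.28 relative to the median gene there at percentile 97.7, with 18 of 25 higher; in cluster 1 it was 0.75 (percentile 99.9) and in the Th2-like cluster -0.37 (percentile 2.38). Costimulatory receptors lay at a median of 0.33 (percentile 76.6, 11 of 15 higher), with Cd28 (0.97) and Cd27 (1.22) higher and Tnfsf8 (CD30 ligand, -1.39) and Slamf1 (-0.95) lower. Tnfsf8 is also one of the 67 genes that differed in all 4 clusters compared under Other observations.

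Over all cells the Treg list also followed the median gene. Foxp3, the Treg master regulator, was at 37.5 CPM (30.4 to 45.8) and 37.8 CPM (28.6 to 49.1). A UMI of it was seen in 3.82% and 4.67% of thinned cells, with no more than 0.0195% from free RNA at that depth, and in 13.1% and 16.0% of unthinned cells. Of 16 members 11 had higher and 5 lower values, with a median log2 ratio of 0.29 (0.14 to 0.35), 0.04 relative, at percentile 71.2. With the cycling-like cluster left out the median was 0.45, 0.22 relative at percentile 94.4, with 13 of 16 higher, and in cluster 1 it was 0.70 (percentile 99.7), with 15 of 15 higher. Izumo1r (folate receptor 4, 0.81) and the integrin Itgae (CD103, 0.83) were higher, and Ebi3, a subunit of interleukin 35, was lower (-1.25). No cluster was named Treg-like.

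Among the 12 genes that lay lowest in the MARCH1-/- host library, Il5, Tigit and Ccr8 are given above. Among these 12 the largest ratio was that of Ccl1, a chemokine that binds CCR8 (ENSMUSG00000020702, chromosome 11, 82176657 to 82305690). It was at 335 CPM (313 to 358) in the WT-host and 14.9 CPM (9.31 to 22.5) in the MARCH1-/- host library, 22.5-fold (14.8 to 36.2) higher in the former. Barcodes under 100 UMIs held Ccl1 at 569 and 159 CPM. Ccr8 (ENSMUSG00000042262, chromosome 9, 120092114 to 120094906) was 10.0-fold (5.15 to 22.3) higher in the WT-host library. Mt2, a metallothionein, was at 75.4 against 10.1 CPM and Arg1, the arginine-degrading enzyme, at 29.3 against 2.70 CPM, from 75 and 4 UMIs. Their log2 ratios were -2.90 and -3.44, and that of Mt2 was -1.98 with the length and GC trend removed. Thinned to 1000 UMIs, Mt2 had 13 and 3 UMIs (-0.93, -3.39 to 0.93) and Arg1 10 and 0, too few for a ratio. Barcodes under 100 UMIs held Arg1 at 14.7 and 27.6 CPM. The ratio of Ccl1 was -5.59 when thinned (109 and 1 UMIs) and -3.55 with the length and GC trend removed, against -4.49. A further 5, Gstp1, Fam177a, Bcl2a1d, Hist1h2ap and Wdr89, share 3' sequence with other genes over 36.0% to 100% of the part searched, so their values, between 3.90-fold (Hist1h2ap) and 11.6-fold (Gstp1) higher in the WT-host library, are uncertain.

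Of the 12 genes that lay highest in the MARCH1-/- host library, 4 share no 3' sequence with another gene. Cxcl3, a neutrophil-attracting chemokine, was at 5.47 CPM (2.99 to 9.17) against 44.6 CPM (34.5 to 56.7), and Stmn2, a microtubule-binding protein, at 4.69 against 37.8 CPM; a UMI was seen in no more than 5.33% of cells for either. Mthfsl was at 10.2 against 58.1 CPM and the histone gene Hist1h2be at 5.47 against 39.2 CPM, the last turning to a log2 ratio of -0.82 when cells were thinned, from 4 and 1 UMIs, and standing at 0.20 without the cycling-like cluster. The other 8 share sequence with other genes over 53.7% to 86.5% of the part searched and are uncertain: Hist1h2an, Hist2h2bb, Cdk2ap1, Hypk, the ribonucleases Rnaset2a and Rnaset2b, and the tubulins Tuba1a (47.6 against 236 CPM) and Tuba1b (148 against 649 CPM). Hist1h2an and Hist1h2ap, near copies of each other among the histone H2A genes, went opposite ways, with log2 ratios of 6.22 and -1.97. Outside the cycling-like cluster Hist1h2an had 0 and 2 UMIs, too few for a ratio, Hist1h2ap was at -3.67 and Tuba1b at 0.99.

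Genes of naive and central memory cells as a list were higher in cells from MARCH1-/- hosts: 15 of 16 members had higher values, 11 of them with an interval clear of 0, and 13 lay above the median gene. The median log2 ratio was 0.83 (0.63 to 1.02), 0.58 relative, at percentile 99.97. Higher were Klf2, which maintains quiescence and egress (102 against 305 CPM, log2 ratio 1.58), the lymph node homing receptor Ccr7 (10.9 against 58.1 CPM, 2.41; 0.81, -0.23 to 1.82, without the cycling-like cluster, an interval that includes no difference) and the guanine exchange factor Rasgrp2 (1.13); Txk was the 1 lower member (-0.28). Genes of tissue residency and migration lay at 0.43 (0.27 to 0.47), percentile 96.6, with 17 of 25 higher, among them the chemokine receptor Cxcr4 (1.86), the integrin Itgb7 (1.06) and Vim (0.93), while S100a6 (-0.79) and Lgals1 (galectin 1, -0.60) were lower.

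Interferon response and type 1 genes as lists were lower in cells from MARCH1-/- hosts. Of 32 interferon response genes 25 had lower values, 13 of them with an interval clear of 0, with a median log2 ratio of -0.26 (-0.46 to -0.17), -0.51 relative, at percentile 0 of the random lists. They included Ifi27l2a (5460 against 2183 CPM, -1.32), the antiviral gene Rsad2 (-1.23), Ifi208 (-2.05) and the transcription factor Irf9 (-0.78). Ifi27l2a, of 463 nt, is one of the 67 genes that differed in all 4 clusters compared under Other observations. For those genes host and library preparation or read processing cannot be told apart. Of 19 type 1 helper and cytotoxic genes 14 had lower values, 7 of them clear of 0, with a median of -0.44 (-0.67 to -0.19), percentile 0.01, and the chemokines Ccl5 (99.6 against 40.5 CPM, -1.30), Ccl4 (-1.14) and Ccl3 (-3.92) among them; Gzmb (0.48) and Nkg7 (0.08) were not lower. Without the cycling-like cluster both directions turned, to medians of 0.07 and 0.02, or -0.15 and -0.21 relative to the median gene there. The type 1 median was also near 0, at -0.04, when cells were thinned to 1000 UMIs, and again at -0.04 (-0.45 to 0.07, percentile 9.56) without clusters 0 and 4. The Th17 list lay at 0.01 (percentile 9.86), with Il17a at 118 against 97.2 CPM. Without the 5% of cells with the largest share of their UMIs in it, that list was at -0.64. The Tfh list lay at 0.12 (-0.13 relative, percentile 23.3), with the signalling adaptor Sh2d1a (1.13) and Slamf6 (1.63) higher.

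**Figure D4:**
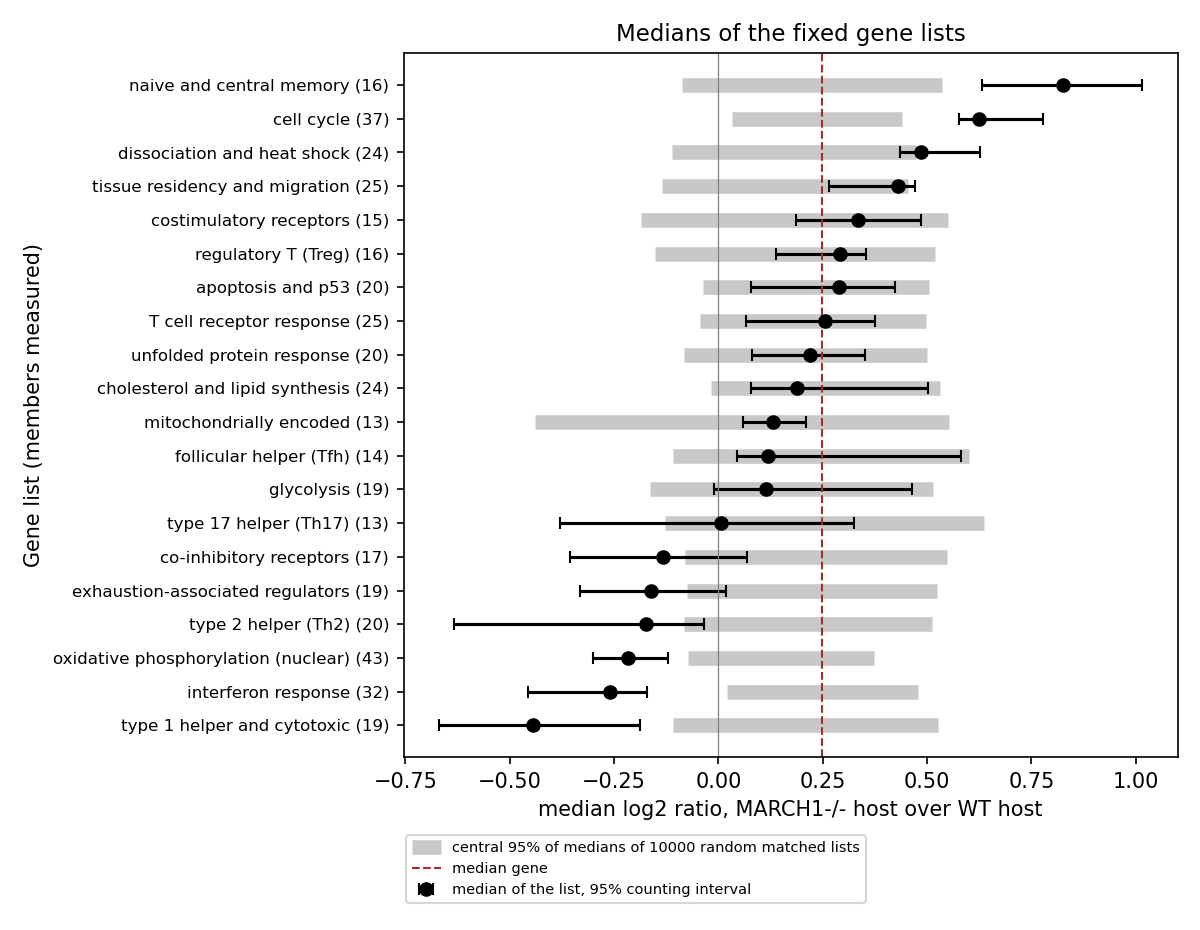
Median log2 ratio of the fixed gene lists (y axis, with the number of members measured), MARCH1-/- host over WT host (x axis), with points for the median, bars for its 95% counting interval, grey bands for the central 95% of 10000 random matched lists and a dashed line for the median gene at 0.25. Naive and central memory (0.83), cell cycle (0.63) and dissociation and heat shock (0.49) lie above their bands. Type 1 helper and cytotoxic (-0.44), interferon response (-0.26), oxidative phosphorylation (-0.22), Th2 (-0.17), exhaustion-associated regulators (-0.16) and co-inhibitory receptors (-0.13) lie below theirs. Without the cycling-like cluster, which cell cycle genes lead, cell cycle turned to -0.50. Type 1 and interferon response were then at 0.02 and 0.07, Th2 at 0.08, exhaustion-associated regulators at 0.14 and co-inhibitory receptors at 0.20, while oxidative phosphorylation was at -0.29.

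Among metabolic and stress genes, glycolysis lay at a median of 0.11 (-0.01 to 0.46, percentile 33.1), or -0.12 without genes that share sequence, with Gapdh (436 against 1235 CPM) higher and Eno1 (-1.94) and Hk2 (-1.47) lower; Gapdh and Eno1 share 3' sequence with other genes over 38.7% and 73.9% of the part searched, so both are uncertain. Nuclear-encoded oxidative phosphorylation genes lay at -0.22 (-0.30 to -0.12), -0.47 relative, at percentile 0.175, with 25 of 43 lower. Short transcripts such as Atp5k (-1.67) and Ndufa1 (-1.0) were lower, while Sdhd (1.59) and Uqcrc2 (1.33) were higher, and with the trend in transcript length and GC content removed the median turned to 0.13. Mitochondrially encoded genes lay at 0.13 (percentile 53.6, 7 of 13 higher), a direction that turned with cells weighted equally (-0.09) and without genes that share sequence (-0.59). The medians were 0.19 for cholesterol and lipid synthesis (percentile 28.6), 0.22 for the unfolded protein response (46.6), and 0.29 for apoptosis and p53 (60.2).

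Immediate-early and heat shock genes, which also respond to tissue dissociation, lay at 0.49 (0.43 to 0.63), 0.24 relative, at percentile 97.8. The AP-1 genes Fos (0.68), Fosb (1.41) and Junb (0.97) and the phosphatase Dusp1 (1.57) were higher in the MARCH1-/- host library, while the chaperone genes Hsph1 (-0.36) and Dnaja1 (-0.17) were lower. Several of these genes also respond to T cell receptor signals. Without the cycling-like cluster the dissociation and heat shock list was at 0.53 (percentile 99.1), beside 0.51 (percentile 97.7) for T cell receptor response. Of the sex-linked genes, Xist was at 804 and 764 CPM, Tsix at a log2 ratio of -1.01, and no Y-linked gene reached 10 UMIs.

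Of the 5 clusters, 2 could be named from the fixed markers, a Th2-like one led by Ccl1, Calca, Plac8 and Il13 and a cycling-like one led by histone genes, Cenpf and Top2a. The Th2-like cluster held 25.4% (20.9 to 30.2) of cells from WT hosts and 13.3% (8.34 to 19.8) from MARCH1-/- hosts, and the cycling-like one 17.4% (13.6 to 21.8) and 28.0% (21.0 to 35.9), a difference of 10.6 percentage points (2.35 to 19.4). Their defining genes differed between the libraries, so shares are also given from a clustering without the Th2 and cycling markers, added after the data were seen. There the Th2-like class held 24.2% (19.8 to 29.0) of cells from WT hosts and 17.3% (11.6 to 24.4) from MARCH1-/- hosts, and the cycling-like class 20.8% (16.7 to 25.4) and 28.0% (21.0 to 35.9), with overlapping intervals in both classes of that clustering. They also overlapped when each library was centred before clustering (Th2-like 19.4%, 15.4 to 23.9, and 14.0%, 8.88 to 20.6, cycling-like 22.5%, 18.2 to 27.2, and 28.0%). With at least 300 UMIs and 150 genes per cell, both limits lowered together, the Th2-like class held 13.2% and 0%. Lower limits only let more barcodes in, yet both shares fell from the main 25.4% and 13.3%. These 2 values thus also depend on which clusters met the naming rule, and the 0% does not show that Th2-like cells were absent. With the markers kept, a clustering resolution of 1.0 put the cycling-like class at 9.69% and 9.33%. That is a smaller part of both libraries than in the main clustering, so this value also depends on which clusters met the naming rule. Cluster 0, led by Ccl5, Klrk1 and Ly6c2, was 91.3% WT-host cells (115 of 126) and cluster 4, led by Gm12840, Tktl1 and Ltb4r1, 95.7% MARCH1-/- host cells (44 of 46), so each may be a library rather than a cell type. Cluster 1, of 84 and 33 cells, mixed markers of interferon-responding, Th17 and Treg cells among its leading genes and stayed unnamed. Of the cells with at least 20000 UMIs, 8 of 9 and 13 of 14 lay in the cycling-like cluster.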

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

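The search of barcodes outside the set of cells, and its threshold of 3-fold, were chosen after the values in cells had been seen. It took the named genes whose level there was at least 3 times that in cells of the same library, with separate counting intervals and more than 3 UMIs there. None of these barcodes is among the cells; the report gives their level of Tox, Ccl1 and Arg1, and the alternative with at most 20% mitochondrial UMIs takes some of them in.

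Barcodes over the mitochondrial limit, which hold damaged or dying cells among others, carried more of several effector and exhaustion-related genes than the cells did. In the WT-host library (73 barcodes, 77977 UMIs) Tox was at 693 CPM there and 209 CPM in cells, Havcr2 at 256 against 78.1, Ifng at 269 against 60.9, Foxp3 at 141 against 37.5, Nr4a3 at 115 against 25 and Cxcl3 at 51.3 against 5.47. Type 2 cytokines went the other way there, with Il4 and Il5 at 0 UMIs (186 and 147 CPM in cells) and Il13 at 89.8 against 789. In the MARCH1-/- host library (26 barcodes, 30420 UMIs) Tox was at 460 CPM against 83.7 in cells, Nr4a2 at 230 against 36.5 and Nr4a3 at 131 against 16.9, while Ifng and Foxp3 (0 UMIs) and Havcr2 (1 UMI) were not raised. The counts behind them were small, from 4 UMIs for Cxcl3 to 54 for Tox in the first library, and from 4 to 14 in the second.

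Barcodes under 100 UMIs, which hold free RNA and fragments of cells, carried Cxcl3 at 26.7 CPM in the WT-host library against 5.47 in its cells. For Cxcl3 the MARCH1-/- host library went the other way, with 9.19 CPM in such barcodes and 44.6 in cells. These barcodes of the MARCH1-/- host library carried Ccl1 at 159 CPM against 14.9 in cells and Arg1 at 27.6 against 2.70. In the WT-host library such barcodes held Ccl1 at 569 CPM against 335 in cells and Arg1 at 14.7 against 29.3.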

How the results depend on the processing

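Alternatives chosen after the data were seen were removing the length and GC trend, leaving out genes with shared 50-mers, the top 5% of cells, clusters 0 and 4 or cells with a Foxp3 UMI, subtracting the low-barcode profile, clustering without markers and the expected thinned share, with and without the cycling-like cluster; the rest were planned. No paired analysis was possible because each group has 1 library. Without Treg-like cells could not be run, as no cluster was so named, nor the fit of free RNA on other cell types. All called cells were T-like, so that alternative changes nothing. The clustering resolutions of 1.0 and 0.3 likewise leave lists, single genes, the cytokine level and shares of cells with a UMI unchanged by construction. Such alternatives are still counted below. The Th2-like class had no value at 20% mitochondrial UMIs or resolution 0.3. Of 209 alternatives of the 14 designed results 174 stayed, 31 moved and 4 reversed. A value stayed when it lay within the counting interval of the main result. Among the 14, the cell numbers and the T-like share were instead judged by a limit on their change, and that share was 100% throughout. For the 14 other lists 241, 30 and 9 of 280 stayed, moved and reversed, and for 38 genes 543, 62 and 3 of 608. Of the 62, 6 have 0 UMIs on one side and are bounds set by the floor of 3 counts. Unless stated, the cause was not tested. Depth limits Tigit (5 UMIs), Arg1 (4) and Il5 (26) in the MARCH1-/- host library.

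Without the cycling-like cluster the Th2 list reversed to 0.0815, cell cycle to -0.50, type 1 to 0.0175, interferon response to 0.0747 and Il10 to 0.21, and Havcr2 moved from -0.85 to -0.31. The co-inhibitory median moved to 0.20, exhaustion regulators to 0.14, T cell receptor response to 0.51, Treg to 0.45 and Th2 cytokines to -0.31. As cell cycle genes lead the cluster left out, the cell cycle value decides nothing. Median-of-ratios scaling subtracts 0.25 from every ratio, so a value between 0 and 0.25 turns by construction. It reversed Tfh (-0.13), mitochondrially encoded (-0.11), cholesterol (-0.0570), unfolded protein response (-0.0255) and Gata3 (-0.0651), and moved co-inhibitory receptors to -0.38, exhaustion regulators to -0.41, T cell receptor response to 0.0106, Treg to 0.0464, cell cycle to 0.38 and Th2 cytokines to -1.63.

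With the mean of per-cell CPM mitochondrially encoded genes reversed to -0.0944, and co-inhibitory receptors stood at 0.0858, T cell receptor response at 0.40, Treg at 0.45, cell cycle at 0.57 and Th2 cytokines at -1.04. Thinned to 1000 UMIs, Hist1h2be reversed to -0.82 (4 and 1 UMIs), type 1 moved to -0.0418, and the values were 0.18 for co-inhibitory receptors, 0.56 for T cell receptor response, 0.49 for cell cycle and -1.06 for Th2 cytokines. Without the 5% of cells with the largest share of their UMIs in the list, T cell receptor response reversed to -0.0149. Without the 5% with the most cytokine UMIs, Th2 cytokines moved to -1.20. Without clusters 0 and 4 co-inhibitory receptors were at -0.36, T cell receptor response at 0.0306 and cell cycle at 0.83. With the length and GC trend removed oxidative phosphorylation reversed to 0.13 and Treg moved to 0.0549. Without genes sharing 50-mers mitochondrially encoded genes reversed to -0.59, glycolysis moved from 0.11 to -0.12 and cell cycle moved to 0.84.

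In percentage points, the difference in the share of cells with a Pdcd1 UMI was -6.54 with at least 300 UMIs and 150 genes per cell and -6.14 without clusters 0 and 4, that for Lag3 was 2.94 at 20% mitochondrial UMIs, 2.58 unthinned and 7.65 without the cycling-like cluster (2.26 expected over all draws), and the cycling-like difference reversed from 10.6 to -0.353 at resolution 1.0 (9.69% against 9.33%). At that resolution the named class held fewer cells of both libraries, so its reversal also depends on which clusters met the naming rule. The Th2-like share was 13.2% against 0% with at least 300 UMIs and 150 genes per cell and 19.4% against 14.0% with each library centred. The 13.2% and 0% also depend on which clusters met the naming rule. The lower Th2 cytokine level kept its direction in all 17 alternatives, from -1.63 to -0.31, and the naive and central memory median stayed between 0.58 and 1.28 in all 20. Both counts include the clustering resolutions and all called cells, which cannot change these values.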

Other observations

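The tests of genes without a shared 50-mer, of transcript length and of the share of Th2-like cells were chosen after the values they measure had been seen; the other tests were set before.

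Within the cycling-like cluster (61 and 42 cells) the libraries differed in more than cytokines. Of 18 Th2 list members 14 had lower values in cells from MARCH1-/- hosts, with a median log2 ratio of -1.40 (-1.64 to -1.12), while 14 of 15 naive and central memory genes had higher values (1.06, 0.89 to 1.36). Ccr7 was at 8.27 against 95.1 CPM and Klf2 at 128 against 342 CPM. The Th17 list lay at 1.02 there, with 7 of 12 members higher. Il10 was at 155 against 21.7 CPM and Havcr2 at 30.7 against 4.08 CPM (26 and 3 UMIs), while Ctla4 was at 440 against 698 CPM. In the Th2-like cluster 13 of 20 Th2 list members had higher values in cells from MARCH1-/- hosts, with a median of 0.28 (0.04 to 0.40), 0.16 relative to that cluster's median gene at percentile 72.5 of random lists; members of this list named that cluster, so its level there decides nothing.

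In cluster 1 (84 and 33 cells) all 15 measured Treg list members had higher values in cells from MARCH1-/- hosts, with a median log2 ratio of 0.70 (0.49 to 0.87), while Foxp3 itself was at 0.02 and the cluster's median gene at 0.14. Several other lists lay high there too: naive and central memory at 0.89, dissociation and heat shock at 0.80, T cell receptor response at 0.75, costimulatory receptors at 0.73, glycolysis at 0.70, type 1 at 0.69 and tissue residency at 0.68. Cytokine UMIs sat in few cells: the top 5% of cells held 67.4% of Il13 UMIs in the WT-host and 66.9% in the MARCH1-/- host library, and 84.4% and 97.9% of Il17a UMIs. Ighm, the B cell heavy chain gene, was at 20.7 and 104 CPM.

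In all 4 clusters with at least 10 cells of each library (0 to 3), 67 genes differed by over 1 on the log2 scale from the median gene. Of these, 64 were lower in the MARCH1-/- host library. A gene needed at least 200 UMIs in all and 20 in each cluster, both libraries together. Cluster 0 held 115 cells from WT hosts and 11 from MARCH1-/- hosts, so genes high only in the latter could hardly reach 20 there. The count of 64 lower genes is thus partly set by this minimum. Of the 67 genes, 31 had no shared 50-mer. The search took only exact stretches in the last 600 nt of the longest transcript, so it cannot exclude shared reads for these 31. A shared 50-mer was found in 53.7% (41.1 to 66.0) of the 67 against 18.1% of all genes with at least 200 UMIs. Whether shared sequence explains most of them stays open. Over all cells 98.5% of the 67 genes differed by over 1 before any correction. The share was 67.2% (54.6 to 78.2) after the trend with transcript length was removed and 98.5% after that with GC content. These trends, taken over all genes, were weak (Spearman -0.105 for length, 0.0971 for GC), and the 67 were picked for a large difference. Most could stay over 1 whatever the cause, so the test decides neither, and a part that goes with length stays open. The 131 genes with a principal transcript under 600 nt had a median log2 ratio of -0.76, against 0.25 for the median gene. Host genotype and library preparation or read processing cannot be told apart for these genes with 1 library per group, so an effect of the host also stays open, untested.

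The lower sum of Il4, Il5 and Il13 in the MARCH1-/- host library kept its direction in both checks made. Its log2 ratio was -1.50 (-1.63 to -1.38) with the length and GC trend removed and -1.20 (-1.41 to -1.0) without the 5% of cells with the most cytokine UMIs. With that trend removed Il4 alone went from -1.28 to -0.56 and Il13 from -1.24 to -1.54. Thinned to 1000 UMIs, Il4 was at -0.44 (-1.42 to 0.46), which includes no difference. A smaller share of Th2 cells at an equal level per cell cannot be told apart from a lower level per cell. In the Th2-like cluster the ratio of the sum was 0.25 (0.09 to 0.40), but Il13 helps define that cluster. Il5 alone was lower there in cells from MARCH1-/- hosts (265 against 80.9 CPM, 162 and 16 UMIs), though 5 of 89 WT-host cells held 115 of its UMIs. In the cycling-like cluster the ratio of the sum was -3.97 (-4.34 to -3.62), which fewer Th2 cells among the cycling cells would give as well. An effect of the host stays open too, untested, as host genotype, animal and library all differ in the 1 contrast.

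Clusters 0 and 4, each nearly all from 1 library, may reflect library-wide differences in gene levels rather than cell states. When 113 genes that differ in clusters 1, 2 and 3 were left out of the clustering, the new cluster that took 38 of the 44 MARCH1-/- host cells of cluster 4 held 63.1% (53 to 72.4) WT-host cells. With random genes matched in number and expression left out instead, in 10 draws, the median was 5% (lowest 4.88, highest 34.5). The 113 genes, unlike the random ones, were chosen for differing between the libraries, so leaving them out tends to mix the libraries whatever the cause. The split of cluster 4 thus rested at least in part on genes that also differ in other clusters. The test cannot tell library-wide differences from cell states. What made the 113 genes differ, host or library, stays open.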
